A study of Homo sapiens with 24 samples.

How the data were processed

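Total RNA from Huh7.5.1 hepatoma cells treated with silymarin or DMSO for 4, 8 or 24 h was hybridised to Affymetrix Human Gene 1.0 ST arrays, per the labels' protocols. The authors deposited log2 expression values made with RMA and the oligo package, per the submitters' processing notes, which give no version. RMA corrects background, normalizes by quantiles and summarises probes on the log2 scale. The genome build was not given in the sources used here, and no coordinates were used. The values were used as deposited, without further normalization.

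The table held 28869 probe sets. The platform annotation paired 19302 of them with 1 gene symbol and 1729 with several, and 7838 were not listed in it. Probe sets with 1 symbol were tested, and where a gene had several, as 757 genes did, the one with the highest mean over all 24 arrays was kept. This left 18274 genes. Symbols were looked up by gene number in the reference table, which changed 0 symbols, and 31 of the probe sets with 1 symbol were not in that table.

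The labels gave 6 groups, DMSO and silymarin at 4 h (4 and 4 arrays), 8 h (5 and 3) and 24 h (5 and 3). One limma model with the 6 group means was fitted to all 24 arrays with lmFit and eBayes in limma 3.58.1 and R 4.3.3, with 18 residual and 5.04 prior degrees of freedom. Contrasts compared silymarin with DMSO at each time point, the change of that difference between time points, and DMSO at 8 h and 24 h with DMSO at 4 h. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the genes tested, and the threshold was an adjusted p of 0.05 with no fold minimum. Intervals are 95% confidence intervals from the moderated fit.

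The 30 gene lists covered stress, inflammation, metabolism, proliferation, hepatocyte genes and markers of other cell types, and 619 of their 678 entries were measured. Each list was tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the 30 lists. Camera with an estimated correlation and fry were alternatives. Members of a list can vary together, so counts of members above 0 are not counts of independent observations. The comparisons, tests, lists, alternatives and the rule for named genes were chosen before the data were examined. The rule took the 10 genes with the largest rise and the 10 with the largest fall among genes that passed and whose groups did not overlap, and the 4 members of each list with the smallest p at each time point. For the interactions and the DMSO comparisons it took 5 genes per direction among those that passed. No gene passed, so named genes come from the lists, and the text prints examples from the lists that passed camera.

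Alternatives were arrays re-centred to 1 median, repeated quantile normalization, cyclic loess, leaving out dim genes, all probe sets and the mean of a gene's probe sets. Dim genes had every group mean under 6.474 on the log2 scale. For the correlations of fold changes, they had a mean over all arrays under 6.474. Further alternatives were limma with trend and robust settings, array weights, a fit with only the groups compared and the replicate number as a block. The last were an adjusted p under 0.01, a change of at least 2-fold, and leaving out each array in turn. An F-test over the 6 groups and the silymarin effect averaged over the 3 time points were added after seeing the data. Counts of genes and lists were also obtained for other splits of the same arrays, all of them or 100 drawn at random. Similarity between arrays was compared with 10000 permutations of the labels.

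The scripts were tested on simulated data with 200 changed genes among 18274. With changes of 1 on the log2 scale added to the deposited values, 98.5% were recovered at 4 h, 95.5% at 8 h and 97.0% at 24 h. For changes of 0.5 the shares were 86.6%, 89.6% and 83.6%. The changed genes were drawn at random from all genes, whose median SD within groups was 0.123. These shares cannot be carried over to genes with a wider spread. CXCL10, for example, differed by 1.01 (SE 0.68) at 4 h, with limma's adjusted p = 0.99993. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No array was left out of the main comparisons.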

Results

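Gene expression was measured in Huh7.5.1 cells, a human hepatoma line, after treatment with silymarin, an extract of milk thistle seed, or with its solvent DMSO. Every sample title carries the word novirus. Each of the 24 samples was hybridised to its own Affymetrix Human Gene 1.0 ST array. After 4 h there were 4 arrays labelled DMSO and 4 labelled silymarin. After 8 h there were 5 labelled DMSO and 3 labelled silymarin, and after 24 h again 5 and 3. The median log2 value of an array lay between 7.04 and 7.18. The silymarin dose was not stated, and nothing in the labels says that replicates came from separate cultures, so the p-values measure spread between samples. The number of arrays limits the precision of each group mean. Expression was compared for 18274 genes with limma, and for 30 gene lists with limma's camera.

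The comparison at 4 h asked how gene expression responded soon after silymarin was added. Inflammatory genes had the higher mean in the arrays labelled silymarin. The NF-kB list holds chemokines and other targets of this inflammatory transcription factor, and 27 of its 34 measured members lay above 0, with a median log2 difference of 0.24. It passed camera with a preset correlation (adjusted p = 9.28e-09), but adjusted p = 0.997 with an estimated correlation. The neutrophil chemokine CXCL8 averaged 10.46 ± 0.27 (SD, n = 4) in silymarin and 9.64 ± 0.59 (SD, n = 4) in DMSO, a difference of 0.81 (SE 0.41). CXCL6 differed by 0.77 (SE 0.34) and CXCL1 by 0.64 (SE 0.32). CCL20, a chemokine for lymphocytes and dendritic cells, differed by 0.66 (SE 0.34). None of these 4 genes passed the test by itself, and each had limma's adjusted p = 0.99993 over all genes. Without DMSO replicate 1 the difference of CXCL6 was 0.49. In DMSO at 4 h, the stress gene DDIT4 was 9.69 and 10.005 in replicates 1 and 4, with CXCL8 at 9.07 and 10.03. Replicates 2 and 3 had DDIT4 at 7.72 and 7.64 and CXCL8 at 10.27 and 9.21. In silymarin, DDIT4 was 10.34 in replicate 1, with CXCL8 at 10.33. The other silymarin arrays had DDIT4 from 7.60 to 8.05 and CXCL8 from 10.22 to 10.83. An effect of silymarin was not separated from this uneven share of arrays with high DDIT4.

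No gene passed at 4 h. limma called 0 genes higher and 0 lower at an adjusted p under 0.05, while 453 genes had an unadjusted p under 0.05, where 914 would be expected by chance. The number of genes whose 4 silymarin arrays all lay above or all below the 4 DMSO arrays was 399, or 2.18% of genes, against 2.86% expected by chance. ATF4 targets, which belong to the integrated stress response, had a median difference of -0.05 over 41 members (adjusted p = 0.727). NRF2 antioxidant targets had a median of -0.01 over 22 members (adjusted p = 0.911). Interferon-stimulated genes had a median of 0.00 (adjusted p = 0.954). The 29 lists that did not pass had medians between -0.06 and 0.06, and adjusted over the list alone 0 members of any list were called. In place of the 1 list, 2, 5 and 7 lists passed without DMSO replicates 2, 3 and 4, and 4 and 2 without silymarin replicates 1 and 3.

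The comparison at 8 h addressed a later point of the same time course. The arrays labelled silymarin had higher means for secretory pathway, inflammatory and acute phase genes. All 24 measured chaperones and degradation factors of the endoplasmic reticulum lay above 0, with a median log2 difference of 0.09 (adjusted p = 3.43e-07, but adjusted p = 0.364 with an estimated correlation). PDIA6, a protein disulfide isomerase, averaged 12.02 ± 0.05 (SD, n = 3) in silymarin and 11.83 ± 0.05 (SD, n = 5) in DMSO. CRELD2 differed by 0.21 (SE 0.09). The NF-kB list had a median of 0.18 with 25 of 34 members above 0 (adjusted p = 2.08e-05, but adjusted p = 0.386 with an estimated correlation). CCL20 differed by 0.86 (SE 0.36) and the superoxide dismutase SOD2 by 0.35 (SE 0.15). DMSO replicates 1 and 4 at 8 h had the lowest values of all 24 arrays for CXCL10, CXCL8, TNFAIP3 and HP. CCL20 was 9.46 and 9.59 in these 2 arrays and at least 11.01 in the other 3 DMSO arrays, and SOD2 was 9.71 and 9.58 against at least 10.22. In DMSO at 8 h, the stress gene DDIT4 was 9.67, 10.28 and 10.11 in replicates 1, 4 and 5. There CXCL10 was 5.11, 4.57 and 6.07. Replicates 2 and 3 had DDIT4 at 7.86 and 7.50 and CXCL10 at 8.28 and 7.96. Silymarin replicates 1 and 3 at 8 h also had high DDIT4 (10.14 and 10.05), with CXCL10 at 7.98 and 6.37, against 7.90 in replicate 2.

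Acute phase and complement genes, which liver cells secrete in inflammation, had 16 of 20 members above 0 at 8 h (adjusted p = 0.000100, but adjusted p = 0.364 with an estimated correlation). Haptoglobin, HP, differed by 1.07 (SE 0.33), the largest positive difference of any gene at 8 h. HP was 7.78 and 7.30 in DMSO replicates 1 and 4 and at least 8.47 in the other 3 DMSO arrays. The heme carrier HPX differed by 0.39 (SE 0.15), or 0.25 without DMSO replicate 4. NRF2 antioxidant targets had 17 of 22 members above 0 (adjusted p = 0.00163, but adjusted p = 0.382 with an estimated correlation), and the quinone reductase NQO1 differed by 0.40 (SE 0.16), or 0.26 without DMSO replicate 4. Cholesterol synthesis genes had 18 of 19 members above 0, with a median of 0.10 (adjusted p = 2.99e-05, but adjusted p = 0.364 with an estimated correlation). IDI1 differed by 0.17 (SE 0.09) and ACAT2 by 0.20 (SE 0.12). Metallothioneins, which bind zinc and copper, had 8 of 9 members above 0 (adjusted p = 0.0247, but adjusted p = 0.492 with an estimated correlation), with MT1H at 0.20 (SE 0.10). Without silymarin replicate 1 the NRF2 list had adjusted p = 0.367, and the metallothioneins had 0.120 without DMSO replicate 5 and 0.191 without silymarin replicate 2.

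Growth-related lists also stood apart at 8 h. Immediate early genes had 18 of 25 members above 0 (adjusted p = 0.00287, but adjusted p = 0.364 with an estimated correlation), and EGR1, a transcription factor induced by growth signals, differed by 0.65 (SE 0.24). G1/S and DNA replication genes had 23 of 30 members above 0 (adjusted p = 0.000450, but adjusted p = 0.584 with an estimated correlation), and E2F1 differed by 0.24 (SE 0.08). G2/M and mitosis genes had 4 of 30 members above 0 and a median of -0.08 (adjusted p = 0.0423, but adjusted p = 0.826 with an estimated correlation). CENPF, a kinetochore protein, differed by -0.18 (SE 0.09), or -0.11 without silymarin replicate 3. Ribosome biogenesis genes had 18 of 22 members above 0 (adjusted p = 8.82e-06, but adjusted p = 0.364 with an estimated correlation), and RRP9 differed by 0.20 (SE 0.07). Nuclear-encoded respiratory chain genes had 23 of 29 members above 0 (adjusted p = 0.000107, but adjusted p = 0.364 with an estimated correlation), and COX7B differed by 0.36 (SE 0.15). The respiratory chain list had adjusted p = 0.268 without silymarin replicate 1, and the G1/S list 0.0849 without DMSO replicate 4 and 0.204 without silymarin replicate 2. The G2/M list had 0.540, 0.345 and 0.194 without DMSO replicates 1, 2 and 3, and 0.387 without silymarin replicate 3.

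No single gene passed at 8 h. limma called 0 genes higher and 0 lower, with 719 genes at an unadjusted p under 0.05 and 914 expected by chance. Genes whose 3 silymarin arrays all lay beyond the 5 DMSO arrays numbered 536, or 2.93%, against 3.57% expected by chance. UGT2B7, a liver glucuronidation enzyme, was the 1 gene called when adjusted over the list alone, among the 11 measured drug metabolism genes. It differed by 0.38 (SE 0.11), with limma's adjusted p = 0.991 over all genes, and this gene was named after its values were seen. Its signal was low, with means of 4.01 in silymarin and 3.63 in DMSO at 8 h. The 19 lists that did not pass had medians between -0.06 and 0.06, the ATF4 targets among them at -0.02 (adjusted p = 0.503).

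The comparison at 24 h addressed the last time point. ATF4 targets had the higher mean in the arrays labelled silymarin, with 39 of 41 members above 0 and a median log2 difference of 0.17 (adjusted p = 5.84e-05, but adjusted p = 0.952 with an estimated correlation). The amino acid transporter SLC7A5 averaged 11.82 ± 0.19 (SD, n = 3) in silymarin and 11.48 ± 0.24 (SD, n = 5) in DMSO. TRIB3, a pseudokinase induced by stress, differed by 0.51 (SE 0.28), or 0.14 without silymarin replicate 1. The chaperones of the endoplasmic reticulum had 21 of 24 members above 0 (adjusted p = 0.0483, but adjusted p = 0.952 with an estimated correlation), with HYOU1 at 0.13 (SE 0.10), or 0.08 without silymarin replicate 1 and 0.23 without silymarin replicate 2. Without silymarin replicate 1 the ATF4 list had adjusted p = 0.842. The chaperone list had 0.172, 0.0642, 0.216 and 0.197 without DMSO replicates 1, 2, 4 and 5, and 0.692 and 0.422 without silymarin replicates 1 and 3.

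Genes of mitosis lay lower at 24 h. None of the 30 measured G2/M members lay above 0, and their median was -0.14 (adjusted p = 4.67e-12, but adjusted p = 0.468 with an estimated correlation). These members varied together over the arrays, so the count does not stand for 30 independent observations. The mitotic kinase NEK2 differed by -0.24 (SE 0.09), or -0.15 without silymarin replicate 1, and the kinetochore motor CENPE by -0.34 (SE 0.15). Metallothioneins had 0 of 9 members above 0 and a median of -0.15 (adjusted p = 8.37e-05, but adjusted p = 0.468 with an estimated correlation), with MT1H at -0.23 (SE 0.10), or -0.37 without silymarin replicate 1 and -0.06 without silymarin replicate 3. Fatty acid oxidation genes had 3 of 17 members above 0 (adjusted p = 0.00424, but adjusted p = 0.312 with an estimated correlation), and PDK4, a kinase that restrains glucose oxidation, differed by -0.30 (SE 0.11). Heat shock genes had 2 of 16 members above 0 (adjusted p = 0.00424, but adjusted p = 0.468 with an estimated correlation), with BAG3 at -0.13 (SE 0.08). Respiratory chain genes had 8 of 29 members above 0 and a median of -0.02 (adjusted p = 0.0483, but adjusted p = 0.923 with an estimated correlation), with UQCRB at -0.14 (SE 0.09). Without silymarin replicate 1 adjusted p was 0.0723 for G2/M, 0.367 for heat shock and 0.213 for respiratory chain genes, and without silymarin replicate 3 it was 0.489 for metallothioneins and 0.124 for fatty acid oxidation. The respiratory chain list also had 0.363 without silymarin replicate 2, and 0.265, 0.216 and 0.197 without DMSO replicates 3, 4 and 5.

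Immediate early genes all had positive differences at 24 h, 25 of 25 (adjusted p = 6.58e-05, but adjusted p = 0.468 with an estimated correlation). DUSP5, a phosphatase that restrains ERK signalling, differed by 0.37 (SE 0.17) and IER2 by 0.19 (SE 0.07). The values were 0.24 for DUSP5 without silymarin replicate 3 and 0.13 for IER2 without DMSO replicate 1. Ribosome biogenesis genes had 21 of 22 members above 0 (adjusted p = 1.30e-05, but adjusted p = 0.468 with an estimated correlation), and BOP1 differed by 0.19 (SE 0.08). Markers of endothelial cells, a cell type absent from a hepatoma line, had 10 of 11 members above 0 (adjusted p = 0.0126, but adjusted p = 0.501 with an estimated correlation). Their levels were low, with TEK at 5.49 ± 0.08 (SD, n = 3) in silymarin and 5.19 ± 0.13 (SD, n = 5) in DMSO. Without silymarin replicate 3 the ribosome biogenesis list had adjusted p = 0.390. The endothelial list had 0.0723 and 0.107 without silymarin replicates 1 and 2, and 0.0547 and 0.0747 without DMSO replicates 2 and 3.

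limma called 0 genes higher and 0 lower at 24 h, with 553 genes at an unadjusted p under 0.05 and 914 expected by chance. RPE65, the visual cycle isomerase of the eye, had the smallest adjusted p, 0.0650 by limma, with a difference of 0.45 (SE 0.07). Its values were low, at least 4.84 in the 3 silymarin arrays and at most 4.59 in the 5 DMSO arrays, and it was named after its values were seen. After repeated quantile normalization RPE65 passed, with limma's adjusted p = 0.0434. Genes with no overlap between the labels numbered 356, or 1.95%, against 3.57% expected by chance. Adjusted over the list alone, 0 members of any list were called. The NF-kB list had a median of 0.02 at 24 h (adjusted p = 0.869).

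**Figure D1:**
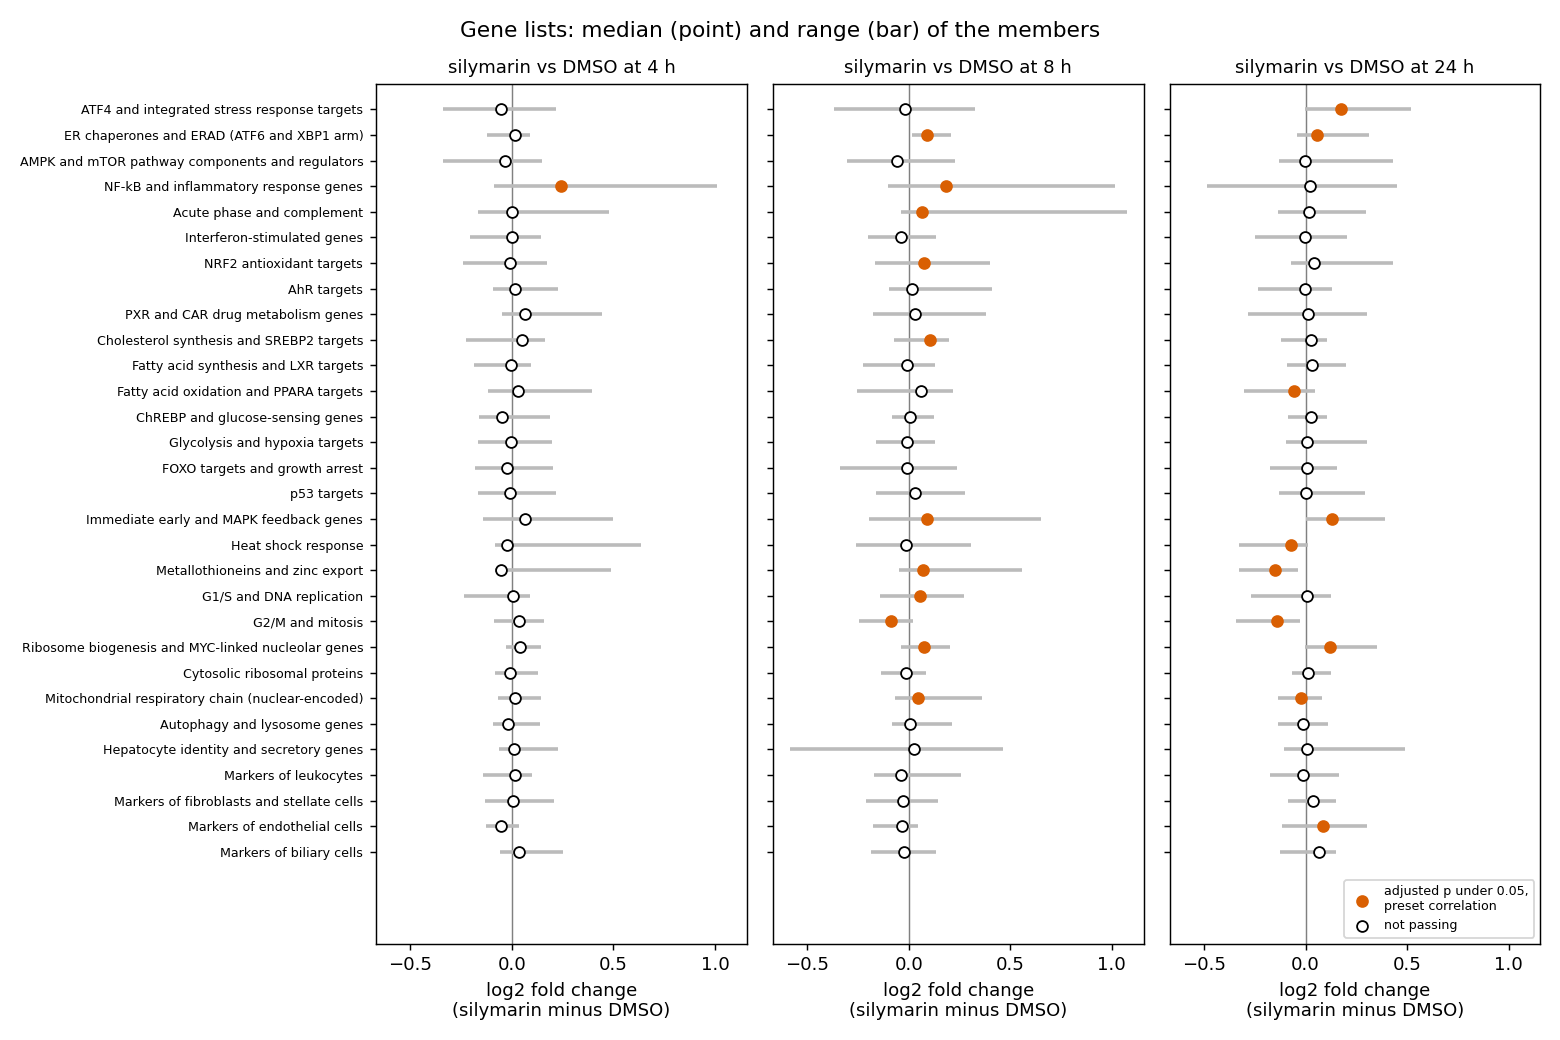
Log2 fold change, silymarin minus DMSO, of the measured members of 30 gene lists at 4, 8 and 24 h. Points are medians, bars run from the lowest to the highest member, and filled points passed camera with the preset correlation, 1 list at 4 h, 11 at 8 h and 10 at 24 h.

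The change of the silymarin effect over time was tested as an interaction. The chemokine CXCL10 had the lowest estimate, -1.50 from 8 h to 24 h and also -1.50 from 4 h to 24 h, and was named after its values were seen. Its differences at 4 h, 8 h and 24 h had SEs of 0.68, 0.70 and 0.70. The smallest limma adjusted p of any gene was 0.950 from 8 h to 24 h and 0.99994 from 4 h to 24 h. CXCL10 was lowest in DMSO replicates 1 and 4 at 8 h, at 5.11 and 4.57. The NF-kB list had a median change of -0.14 from 8 h to 24 h (adjusted p = 0.00542, but adjusted p = 0.758 with an estimated correlation). ATF4 targets had a median change of 0.21 from 4 h to 24 h (adjusted p = 0.00112, but adjusted p = 0.904 with an estimated correlation). G2/M genes had a median change of -0.18 from 4 h to 24 h, with 0 of 30 members above 0 (adjusted p = 1.78e-08, but adjusted p = 0.904 with an estimated correlation). limma called 0 genes in each of the 3 interactions, with 433 genes at an unadjusted p under 0.05 from 4 h to 8 h, 746 from 8 h to 24 h and 551 from 4 h to 24 h. Camera with the preset correlation passed 4, 13 and 8 of the 30 lists in that order, and 0 with an estimated correlation or by fry. From 4 h to 8 h, 0 lists passed without DMSO replicate 3 at 8 h, 1 without replicate 4 of either label at 4 h, and 2 without silymarin replicate 2 at 4 h or replicate 1 at 8 h. From 8 h to 24 h, 7 passed without silymarin replicate 1 at 8 h, and 8 without DMSO replicate 4 at 8 h or silymarin replicate 1 at 24 h. Repeated quantile normalization passed 5 lists from 8 h to 24 h and 5 from 4 h to 24 h, and leaving out dim genes passed 4 from 4 h to 24 h. Across genes, which are not independent replicates, fold changes at 4 h and 8 h had a Pearson correlation of 0.16 and a Spearman correlation of 0.09. In 100 exchanges of the treatment labels within time points, 64 gave a Pearson correlation as far from 0. The Pearson and Spearman correlations were -0.09 and -0.10 for 8 h and 24 h, and -0.005 and -0.05 for 4 h and 24 h, where leaving out dim genes gave a Pearson correlation of 0.014.

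The arrays labelled DMSO gave the background of the time course. Mitotic genes had lower means at 8 h than at 4 h, with 0 of 30 G2/M members above 0 and a median log2 difference of -0.15 (adjusted p = 8.05e-09, but adjusted p = 0.631 with an estimated correlation). G1/S genes had a median of -0.13 (adjusted p = 1.08e-07, but adjusted p = 0.631 with an estimated correlation). At 24 h against 4 h the NF-kB list had 30 of 34 members above 0 and a median of 0.20 (adjusted p = 1.92e-08, but adjusted p = 0.934 with an estimated correlation). CXCL10 differed by 1.12 between these time points, or 0.69 without DMSO replicate 1 at 4 h. limma called 0 genes at 8 h against 4 h, with 1188 at an unadjusted p under 0.05, and 0 at 24 h against 4 h, with 310. Camera with the preset correlation passed 7 and 6 lists, and 0 with an estimated correlation or by fry. At 24 h against 4 h, 1 list passed without DMSO replicate 1 at 24 h, and 3 without DMSO replicate 4 or 5 at 24 h or replicate 4 at 4 h, or after repeated quantile normalization. UGT2B7 was the 1 member called when adjusted over the list alone at 8 h against 4 h, with a difference of -0.33 (SE 0.10) and limma's adjusted p = 0.739 over all genes. The same DMSO arrays at 8 h, with a mean of 3.63, entered this and the silymarin comparison of UGT2B7, and its mean in DMSO at 4 h was 3.96.

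Several stress and inflammatory genes varied widely between arrays of one label. DDIT4, a stress-induced inhibitor of mTOR signalling, had an SD of 1.14 over the 24 arrays, and 8.02% of its variance lay between the 6 labelled groups. CHAC1, which degrades glutathione, had an SD of 1.11. These genes were chosen after their values were seen. At 4 h DDIT4 averaged 8.42 ± 1.29 (SD, n = 4) in silymarin and 8.76 ± 1.26 (SD, n = 4) in DMSO, a difference of -0.34 with a 95% confidence interval from -1.94 to 1.25. At 8 h the difference was 0.23, with an interval from -1.42 to 1.88, and at 24 h it was 0.43, with an interval from -1.21 to 2.08. CHAC1 differed by -0.30, 0.33 and 0.48 at the 3 time points, with intervals from -1.86 to 1.26, from -1.28 to 1.94 and from -1.13 to 2.09. CXCL10 ranged from 4.57 to 9.51 over the arrays and differed by 1.01 at 4 h, with an interval from -0.39 to 2.41, or 0.58 without DMSO replicate 1. Leaving out 1 array turned the sign of the DDIT4 and the CHAC1 difference at each time point.

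**Figure D2:**
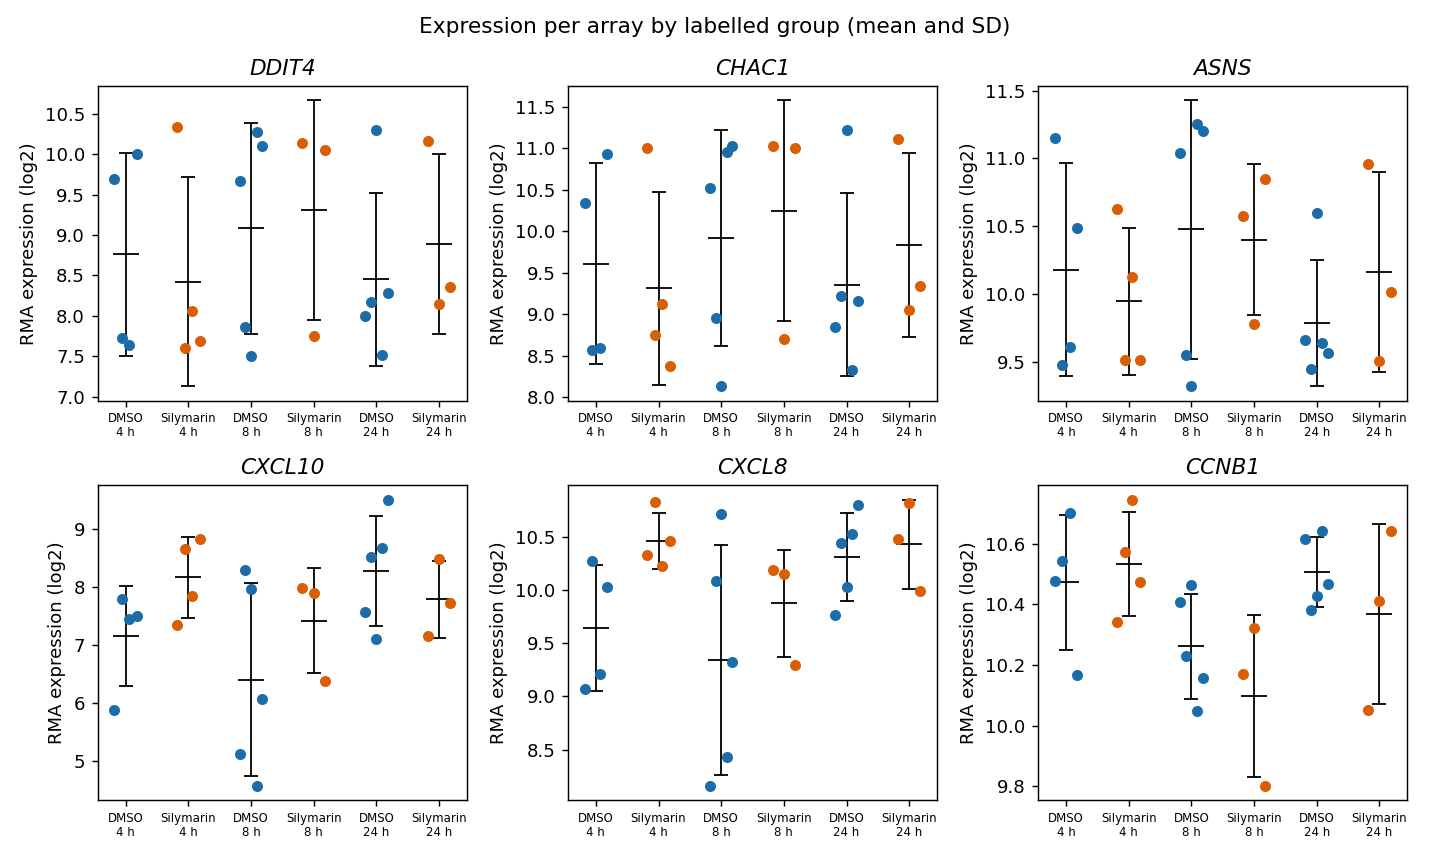
RMA log2 expression of 6 genes in each array, by labelled group, with the mean and SD of the group. DDIT4 and CHAC1 values of arrays with one label lie far apart at every time point, and the genes shown were chosen after their values were seen.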

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

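The split counts for genes and for the lists of the DMSO comparisons, and all tests of the DDIT4 pattern apart from the one on normalization, were chosen after the results were seen.

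DDIT4 stood far from the other arrays of its group in the first silymarin array at 4 h, at 10.34 against 7.60 to 8.05 in the other 3. In the DMSO group at 24 h, DDIT4 was 10.30 in replicate 3 against 7.52 to 8.28 in the other 4. PES1, a ribosome biogenesis factor, was 9.32 in DMSO replicate 4 at 8 h against 9.49 to 9.54 in the other 4. These are 3 of 62 gene and group tests, and chance would give about 3. That rate cannot tell whether these flags are chance, since genes that vary together do not give independent tests. Both DDIT4 values lay above the DDIT4 gap described below. The same 10 arrays lay above the widest gaps of CHAC1, CTH, ASNS and SESN2. The silymarin effect differed between time points for gene lists by camera with the preset correlation, in 4 lists from 4 h to 8 h, 13 from 8 h to 24 h and 8 from 4 h to 24 h, and in 0 lists with an estimated correlation.

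For genes called, limma gave 0 in all 8 comparisons, a count that every split reaches or exceeds by construction, so these counts decide nothing. Splits with as many numbered 35 of 35 at 4 h (highest other 1), 56 of 56 at 8 h (highest 74) and 56 of 56 at 24 h (highest 58). For the interactions 100 of 100 splits did so, with highest counts of 121 from 4 h to 8 h, 1206 from 8 h to 24 h and 29 from 4 h to 24 h. For DMSO at 8 h and 24 h against 4 h it was also 100 of 100, with highest counts of 726 and 0. Few other splits called any gene, 2 at 4 h, 2 at 8 h, 2 at 24 h, 5, 3 and 3 for the interactions in that order, and 4 and 0 for the DMSO comparisons. Counts of genes at an unadjusted p under 0.05 were not fixed in this way. The real labels gave 453, 719 and 553 at 4, 8 and 24 h, and 21 of 35, 32 of 56 and 41 of 56 splits gave more. For the interactions in that order 70, 57 and 64 of 100 gave more, and for the DMSO comparisons 33 and 91. By this measure the labels did not stand apart from other splits.

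For the counts of gene lists passing camera with the preset correlation, other splits of the same arrays show that chance cannot be excluded. At 4 h 34 of 35 splits passed as many as the real 1 list (highest other 14). At 8 h 8 of 56 splits passed as many as the real 11 (highest 13), and at 24 h 20 of 56 passed as many as the real 10 (highest 15). For the interactions the counts were 76 of 100 splits for the real 4 lists (highest 16), 10 of 100 for 13 (highest 16) and 39 of 100 for 8 (highest 15). For DMSO at 8 h and 24 h against 4 h they were 63 of 100 for 7 (highest 15) and 60 of 100 for 6 (highest 14).

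DDIT4 values of arrays with one label lay on both sides of a gap of 1.32 on the log2 scale, with 10 arrays above it and 14 below. The gap was at least 1.3167 under re-centring, quantile and loess scaling, so a leftover shift between the deposited arrays did not make it. RMA had already normalized by quantiles, and array medians lay between 7.04 and 7.18. These scalings could therefore hardly change the gap, and they do not test the earlier steps of RMA. Silymarin as labelled cannot be the whole cause, since both labels had arrays on both sides at all 3 time points, with 4 of 10 silymarin and 6 of 14 DMSO arrays above, and a smaller effect stays open. The replicate number cannot be the whole cause either, since 4 of the 5 numbers had arrays on both sides, but a batch that it marks in part may contribute, since 5 of 6 arrays numbered 1 and 0 of 6 numbered 2 lay above the gap (Fisher's exact p = 0.0326 over the 5 numbers). Labels attached to other columns of the table stay open. The 10 arrays above equal the number labelled silymarin, which is weak evidence noticed in the data. The match is in the total only. At 4 h 1 silymarin and 2 DMSO arrays lay above the gap. The counts were 2 and 3 at 8 h, and 1 and 1 at 24 h. An exchange of labels within time points would therefore not give the match. In column order, arrays above and below the gap alternated from DMSO replicate 5 at 8 h to the last column, but not regularly in earlier columns. The cause of this order was not tested. The similarity of arrays with one label (permutation p = 0.239) decides nothing, as small effects would give it too. Unrecorded differences between cultures, such as nutrient supply, were not tested and stay open, and no array was reassigned.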

How the results depend on the processing

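The F-test over the 6 groups and the effect averaged over time were chosen after seeing the data. They called 0 genes with limma, with 1316 and 518 genes at an unadjusted p under 0.05. Every count of genes was 0 under all alternatives, with 1 exception. Repeated quantile normalization called 1 gene higher at 24 h, RPE65.

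Counts of lists passing camera fell to 0 in all 8 comparisons with an estimated correlation and by fry. Repeated quantile normalization passed 5 lists for the change from 8 h to 24 h, 5 from 4 h to 24 h and 3 for DMSO at 24 h against 4 h, and leaving out dim genes passed 4 from 4 h to 24 h. With the replicate number as a block within each time point, 7 lists passed from 4 h to 8 h, 8 from 8 h to 24 h and 2 from 4 h to 24 h. Leaving out each array in turn gave 1 to 7 lists at 4 h (7 without DMSO replicate 4, 5 without DMSO replicate 3, 4 without silymarin replicate 1, 2 without DMSO replicate 2 or silymarin replicate 3), 10 to 15 at 8 h and 7 to 10 at 24 h. It gave 0 to 6 from 4 h to 8 h (0 without DMSO 8 h replicate 3), 7 to 13 from 8 h to 24 h (7 without silymarin 8 h replicate 1), 6 to 10 from 4 h to 24 h, 6 to 10 for DMSO at 8 h and 1 to 9 for DMSO at 24 h (1 without replicate 1).

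With the block, the correlation of fold changes at 4 h and 8 h was -0.0028 and that at 4 h and 24 h was -0.111. Leaving out dim genes gave 0.014 at 4 h and 24 h. The cause of these changes was not tested. The numbers were not taken as pairs: 4 of 10 same-number pairs of arrays correlated over 0.1, 3 correlated best with their own number, and values ran from -0.14 to 0.43. The mean correlation of arrays with one number was 0.0001 against -0.042 for random groups (permutation p = 0.109), which leaves a link with the number open. Of single list results, 239 kept their side of the threshold and 91 lost it. Of named gene values, 1576 kept their sign and their side of the threshold, and 3 changed sign without passing. No named gene passed in the main fit, so keeping its side means only that it still did not pass.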

Other observations

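The list variability, the gaps and the similarity of arrays were examined after seeing the data.

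Within the lists of stress, inflammatory and mitotic genes, members of one list varied together over the 24 arrays. Each list was examined by itself, so this does not mean that the lists rose together. DMSO arrays at 8 h with high DDIT4 had low CXCL10, as given above. In the ATF4 list, 39 of 41 members loaded one way on a first component that held 87.3% of the list's variance, against a median of 36.8% for random lists. Of its members, 15 were among the 200 most variable genes. Genes were not scaled and random lists were matched on mean level only, so a few variable genes can raise this share. The AMPK and mTOR list, which holds DDIT4 and SESN2, reached 82.1% with 16 of 25 members loading one way. The amino acid genes ASNS and CTH and the stress gene SESN2 each had 10 arrays above their widest gap, the same 10 arrays as DDIT4. In the NF-kB list, 30 of 34 members loaded one way on a component with 82.9% of the variance, against 30.5%, and 10 were among the most variable genes. CXCL10 had the largest SD of any gene, 1.19. All 30 G2/M members loaded one way, with 80.8% of the variance against 39.4%. Cytosolic ribosomal proteins were steady, with a median SD of 0.060 at the 0.01 percentile of random lists.

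The share of variance between the 6 labelled groups differed from gene to gene. It was 35.5% for CXCL10, 37.9% for CXCL8, 42.6% for CXCL1, 44.3% for CCL20 and 36.9% for TNFAIP3, against 8.02% for DDIT4 and 8.45% for CHAC1. Other members of the NF-kB list had lower shares, with 24.4% for CXCL2, 26.8% for IL32 and 30.2% for ICAM1. Members of this list varied together, so their shares are not independent observations. The F-test over the groups called 0 genes with limma, with 1316 at an unadjusted p under 0.05. Over all genes, the median SD was 0.127 over the arrays and 0.123 within groups, and the median share between groups was 23.2%, against 21.7% by chance. The mean correlation between arrays, across genes with gene means removed, was -0.016 within groups and -0.046 between groups. The closest pair was silymarin replicate 3 at 4 h and silymarin replicate 3 at 24 h, with a correlation of 0.62. DDIT4 lay above its gap in 4 of 10 silymarin arrays and 6 of 14 DMSO arrays.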
